A study of Arabidopsis thaliana with 24 samples.

How the data were processed

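Transcript levels were measured on 24 Affymetrix arrays of Arabidopsis thaliana, with biotin-labelled total RNA taken from plants 28 d old. In their fifth-youngest leaf, the leaf tip is the top 2.5 mm of the lamina and the petiole base is the lowest 1.5 mm of the petiole. The authors deposited RMA values made with Expression Console at the core gene level, and the range of the deposited values, from -0.479 to 13.4 with a median of 2.96, shows a log2 scale. RMA corrects the background, makes the distribution of signals equal across arrays and summarises probes by median polish, so it removes any shift shared by all genes of an array. The software version and annotation release were not stated, and scanner files were not used here. For arrays the number of replicates, 3 per group, limits the precision.

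The file held 38408 probe sets. The platform annotation paired 16746 of them with 1 gene and 758 with several, and it did not list the other 20904, which are unnamed here. The tests ran on the 17504 probe sets with a gene, and genes were named from probe sets with 1 gene only. The reference gene table held 16601 of these single-gene probe sets, of which 1777 had a symbol of their own and 14824 carried a locus name only. It lacked 145, which keep the name in the platform annotation. No coordinates are given, since the genome build behind the array's design was not stated.

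All 24 arrays were fitted in limma 3.58.1 (R 4.3.3) with 1 mean for each of the 8 groups and 16 residual degrees of freedom, followed by eBayes without trend. A probe set was called at a Benjamini-Hochberg adjusted p below 0.05 over the probe sets of 1 comparison, and all tests were two-sided. There were 14 comparisons: each treatment against control in each tissue, whole far-red against local far-red and local far-red against touch in each tissue, leaf tip against petiole base in control plants, and the difference of each treatment effect between the tissues. A fold change is a difference of log2 means, given with its moderated standard error (SE), while group means are given with their SD (n = 3 arrays).

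The comparisons, the rule for named genes and 27 gene lists were chosen before the data were examined. The rule named IAA29, PIL1, HB-2, HFR1, YUC8, YUC9, IAA19, CML24 and TCH4 in each treatment comparison, the 8 largest rises and 8 largest falls among called genes, and up to 4 called members of each list. In the other comparisons it named the 5 largest rises, the 5 largest falls and up to 3 called members of each list. Of those 9 genes only IAA29 has a named probe set. The lists held 447 loci, of which 60 were measured under a name. With at least 3 measured members, 9 lists were tested with camera at a preset correlation of 0.01, and the same test with an estimated correlation was the alternative. Of the other lists, 11 had 1 or 2 measured members, and 7 (SAUR genes, brassinosteroid, jasmonate, heat shock, and epidermis, phloem, and xylem and cambium markers) had none. Families of genes that share a symbol stem, with at least 5 members, were added after the annotation had been read.

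The test of local far-red in the petiole base was tried on simulated data with the spread of each probe set in these arrays. It recovered 16% of probe sets set to change 1.5-fold, 84% of those at 2-fold and 100% of those at 3-fold. Of its 152 calls 2 were false. The simulated noise was independent between probe sets, without deviations shared across an array. It therefore does not give the share of false calls in the real arrays. Within groups, arrays correlated at 0.980 to 0.992 across probe sets, which are not independent replicates.

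The labels state 3 independent biological replicates and that tip and base came from the same leaf, but not what a replicate number marks. The numbers were checked by correlating the deviations of same-numbered arrays from their group means, across probe sets. For local far-red against control in the petiole base the correlations were 0.100, 0.183 and 0.437, all above 0.1, so that comparison is also given with the number as a block. In the other comparisons at least 1 pair fell at or below that level. The alternatives were the replicate block, cyclic loess on top of RMA, a filter that left out the dimmest 30% of probe sets, all probe sets of the file, a variance trend with robust estimation, only the groups compared, and leaving out each array in turn.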

Results

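The data are 24 arrays of Arabidopsis thaliana in 8 groups of 3: leaf tip and petiole base under control white light, local far-red (FR), whole FR and touch. Local FR enriched far-red light at the leaf tip alone, to a red to far-red ratio (R:FR) of 0.05 against a background of 2.3, and whole FR enriched the whole rosette. Photosynthetic light was 140 µmol per square metre and second in all groups, with 9 h of light a day at 20 °C, and tissue was taken 5 h after the start of treatment. Far-red enrichment is the light signal of neighbouring leaves, which plants read through phytochrome. The first principal component held 60.2% of the variance and parted leaf tip from petiole base, and the second held 8.62%.

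**Figure D1:**
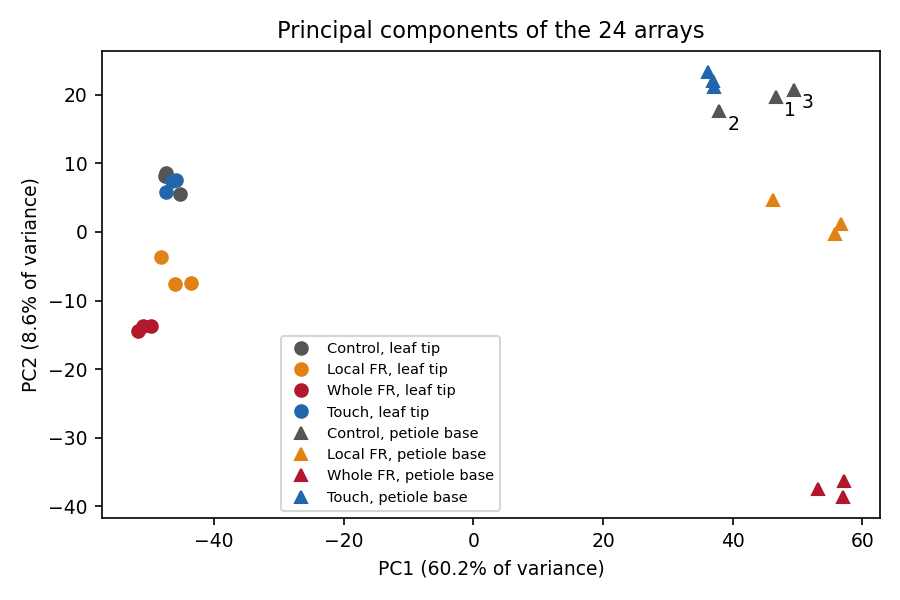
Scores of the 24 arrays on the first and second principal components of log2 values, with circles for leaf tip, triangles for petiole base, colours for treatment and replicate numbers beside the control petiole base arrays. Control petiole base replicate 2, at 37.9 on the first component, lies nearer to the touch arrays, at 36.2 to 37.1, than replicates 1 and 3 do, at 46.6 and 49.4.

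Leaf tip against petiole base in control plants asks how the 2 ends of the leaf differed before any treatment. SWEET11, a sucrose transporter gene, was higher in the tip by 7.80 on the log2 scale (SE 0.18), with a mean of 9.07 ± 0.12 (SD, n = 3) in the tip and 1.27 ± 0.30 in the base. That is near the low end of the signals, whose 5th and 25th percentiles in the control base were 0.91 and 1.18, so here and for other genes with 1 level that low the log2 difference may understate the true one. PYK10, a beta-glucosidase of endoplasmic reticulum bodies, had a log2 difference of -8.32 (SE 0.28) and so was higher in the base, as were the anthocyanin genes DFR, at -7.90 (SE 0.32), and AT5MAT, at -6.61 (SE 0.20). All 3 measured members of the light harvesting list were higher in the tip, among them LHCB4.2 by 1.12 (SE 0.14), and so were all 3 of the chlorophyll biosynthesis list. These lists were shifted in camera at an adjusted p of 0.00408 and 0.0134, and at an adjusted p of 0.116 for each with an estimated correlation. The guard cell gene FMA was higher in the tip by 1.26 (SE 0.21), and the mitotic kinase gene AUR1, with a difference of -2.74 (SE 0.28), was higher in the base.

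Of genes that matter for the light response, IAA29 was higher in the tip by 3.6 (SE 0.31), PIF7 by 2.70 (SE 0.16) and the auxin synthesis gene YUC2 by 2.12 (SE 0.23). In limma 5028 of the 17504 probe sets were called, 2369 higher in the tip and 2659 higher in the base.

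Local FR against control in the leaf tip asks what the lit tissue itself did. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose most among single-gene probe sets, by 4.70 on the log2 scale (SE 0.53, adjusted p = 9.973e-06), from 1.83 ± 0.36 to 6.53 ± 0.23 (SD, n = 3). The Aux/IAA repressor genes IAA34 and IAA29 rose by 3.62 (SE 0.18) and 2.90 (SE 0.31), and the loci AT2G47780 and AT3G21330 by 4.4 and 3.82. YUC2 rose by 0.99 (SE 0.23), the other 3 of 4 measured auxin biosynthesis genes did not pass the test, and that list was not shifted (camera adjusted p = 0.430). YUC4 and YUC11 stood at 1.55 and 1.14 in the control tip, near the low end of the signals. Of 9 measured auxin response genes 2 rose, none fell and 7 did not pass the test (camera adjusted p = 0.00313, and 0.0140 with an estimated correlation). Among those 7, IAA20, IAA30, GH3.4, LBD16 and LBD29 stood at 0.79 to 1.43 in the controls of both tissues. At such levels a fall can hardly show. Of 3 shade avoidance markers IAA29 and FHL rose, FHL by 1.58 (SE 0.27), and HAT2 did not pass the test (camera adjusted p = 7.803e-08, and 0.000237 with an estimated correlation). Adjusted over the list alone, all 3 rose. IAA29 belongs to both the auxin response and the shade avoidance list, so those list calls rest partly on the same gene.

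Other list members moved too. COR15A, a gene of cold and abscisic acid responses, rose by 1.3 (SE 0.19), EXPA16 by 1.17 (SE 0.29) and XTH33 by 0.88 (SE 0.21), both of the last coding for cell wall loosening proteins. Under touch in the tip COR15A changed by 0.82 (SE 0.19) and EXPA16 by 1.06 (SE 0.29). Both treatments are measured against the same 3 control arrays, so whether these rises are particular to light stays open. Neither touch change passed the test over all probe sets, but both rose adjusted over their list alone. EXPA16 stood at 3.819, 4.291 and 5.493 in control, against 5.549, 5.963 and 5.613 under local FR. PIF7, a transcription factor gene of shade growth, fell by 0.88 (SE 0.16). In limma 359 probe sets were called, 205 higher and 154 lower, and 167 changed at least 2-fold. Fitting only the groups compared, which leaves fewer arrays to estimate the spread, gave 126. Without local FR leaf tip replicate 2 the count was 213, and without replicate 3 it was 234.

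Whole FR against control in the leaf tip asks the same under light that reached the whole plant. GH3.3 rose by 5.16 (SE 0.53) and IAA29 by 3.34 (SE 0.31), to 8.19 ± 0.26 (SD, n = 3). Of the 9 auxin response genes 2 rose and none fell, and the list was not called (camera adjusted p = 0.0661, and 0.129 with an estimated correlation). All 3 shade avoidance markers rose, FHL by 2.54 (SE 0.27) and HAT2 by 0.66 (SE 0.19), with a camera adjusted p of 8.252e-07, and 0.000533 with an estimated correlation. COR15A rose by 1.35 (SE 0.19), KIN1 by 1.12 (SE 0.23) and the ethylene transcription factor gene EIN3 by 0.56 (SE 0.15). PIF7 fell by 1.3 (SE 0.16), and both measured cytokinin response regulators fell, RR16 by 1.17 (SE 0.24) and ARR15 by 1.15 (SE 0.30). Of the 13 cell wall genes XTH33 and EXPA16 rose, by 1.51 and 1.02, and EXPA15 fell by 0.97 (camera adjusted p = 0.663). The deepest fall among single-gene probe sets was at AT1G31690, which fell by 4.95 (SE 0.38) from 8.64 ± 0.06. Limma called 1384 probe sets, 702 higher and 682 lower, and 696 when only the groups compared were fitted.

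**Figure D2:**
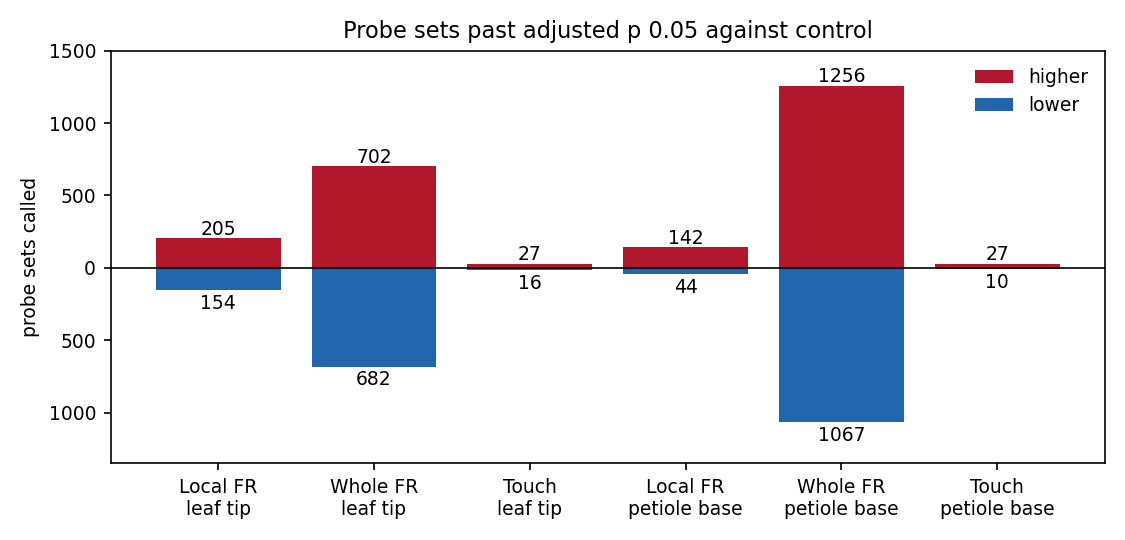
Probe sets called against control, as bars above 0 for those higher and below 0 for those lower, in each treatment and tissue. Whole FR in the petiole base has the most, with 1256 higher and 1067 lower, and touch the fewest.

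Local FR against control in the petiole base asks whether light at the tip reached gene expression at the other end of the leaf. The largest rises were at AT5G57760 by 2.72 (SE 0.23), AT1G44830 by 2.21 (SE 0.27) and AT5G12940 by 2.1 (SE 0.20). Among cell wall genes, EXLA1 and EXLA2, which code for expansin-like proteins, rose by 1.69 (SE 0.19, adjusted p = 3.817e-05) and 1.56 (SE 0.21), EXLA1 from 3.01 ± 0.13 to 4.70 ± 0.27 (SD, n = 3), and XTH33 rose by 0.98 (SE 0.21). Of 13 measured expansin and xyloglucan endotransglucosylase genes 3 rose and none fell, or 7 rose and 1 fell adjusted over the list alone, and the list shifted up (camera adjusted p = 2.492e-07, and 0.000209 with an estimated correlation). IAA29 rose by 1.67 (SE 0.31) and HAT2 by 0.99 (SE 0.19), and the shade avoidance markers shifted up (camera adjusted p = 3.698e-07, and 0.000256 with an estimated correlation). The auxin response list was not called (camera adjusted p = 0.155, and 0.196 with an estimated correlation).

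WAG2, which codes for a kinase that acts on auxin efflux carriers, rose by 1.35 (SE 0.32), and MGL, a methionine gamma-lyase gene, by 2.04 (SE 0.23). GH3.3 did not pass the test here, at a log2 change of -0.06 (SE 0.53), and its control arrays spread widely, at 2.656, 2.047 and 5.218 against 2.62, 2.956 and 4.162 under local FR. Limma called 186 probe sets, 142 higher and 44 lower. With the replicate number as a block it called 220, and with only the groups compared 27. Without local FR petiole base replicate 2 the count was 78. On a score along the tip-minus-base difference of the touch arrays the local FR petiole arrays averaged -0.049 ± 0.039 (SD, n = 3), control 0 ± 0.033 and whole FR -0.003 ± 0.023. In limma on the petiole base arrays alone 110 of the 186 stayed called, and 29 with that score added as a covariate, a choice made after seeing the data. With the covariate all 186 kept their sign, at a median of 0.953 of their fold change, and the median SE was 0.214 in place of 0.176.

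Whole FR against control in the petiole base gave the most calls of the treatment comparisons. IAA29 rose by 5.50 (SE 0.31, adjusted p = 4.032e-11), from 1.24 ± 0.05 to 6.74 ± 0.47 (SD, n = 3), and FHL by 3.32 (SE 0.27). Of the 13 cell wall genes 8 rose and 3 fell (camera adjusted p = 1.082e-07, and 0.000162 with an estimated correlation). XTH33 rose by 3.6 (SE 0.21), EXLA1 by 3.57 (SE 0.19), EXLA2 by 2.86 (SE 0.21) and XTH16 by 2.75 (SE 0.27). EXPA15 fell by 1.35, EXPA4 by 1.33 and EXPB3 by 1.22. MGL rose by 4.85 (SE 0.23). Of 9 auxin response genes IAA29 and WES1 rose, WES1 by 1.41 (SE 0.31), with a camera adjusted p of 0.0436. That call was lost at an adjusted p of 0.0620 with an estimated correlation.

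Pigment genes went down there. All 3 measured flavonoid and anthocyanin genes fell, DFR by 4.23 (SE 0.32) from 9.92 ± 0.21 to 5.69 ± 0.33 (SD, n = 3), UGT78D2 by 1.81 (SE 0.36) and UGT78D1 by 0.73 (SE 0.16), with a camera adjusted p of 1.471e-05, and 0.000859 with an estimated correlation. UF3GT and AT5MAT, which code for enzymes that decorate anthocyanins, fell by 4.2 (SE 0.34) and 3.35 (SE 0.20). Of 3 chlorophyll synthesis genes PORB and CHLM fell, by 0.94 (SE 0.10) and 0.54 (SE 0.12), with a camera adjusted p of 0.000626, and 0.0300 with an estimated correlation. ARR15 fell by 1.32 (SE 0.30) and HYH, a light-response transcription factor gene, rose by 1.3 (SE 0.19). Limma called 2323 probe sets, 1256 higher and 1067 lower, of which 747 changed at least 2-fold.

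**Figure D3:**
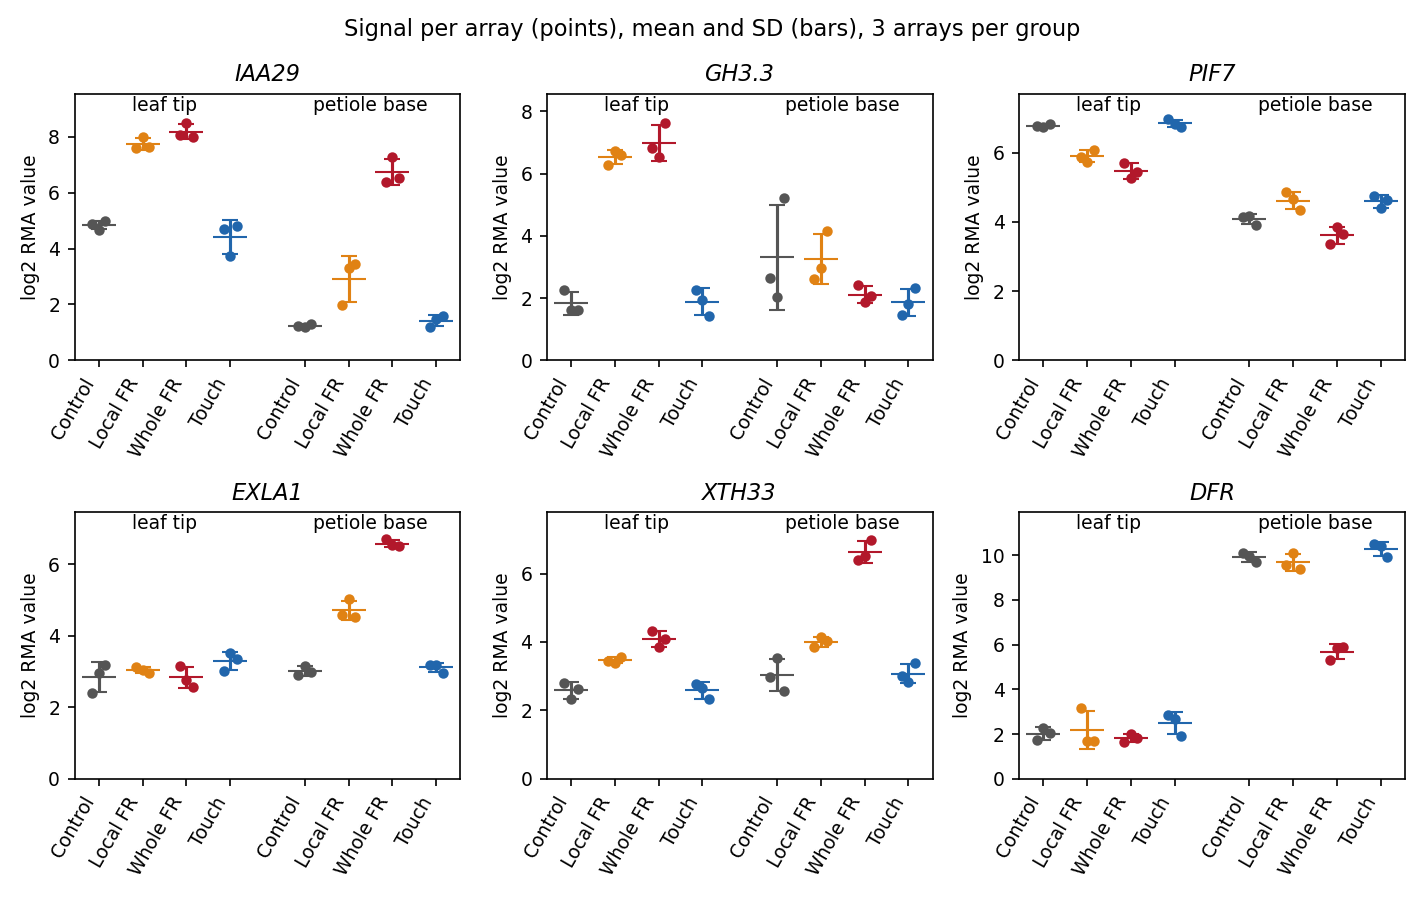
Log2 RMA value per array (points) with the mean and SD of 3 arrays (bars) for 6 genes in the 8 groups. EXLA1 is raised in the petiole base under both FR treatments, to 4.70 and 6.58 from 3.01, and DFR is lowered there under whole FR, to 5.69 from 9.92.

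Touch against control asks what touch did without any change of light. In the leaf tip AT4G17470 rose by 2.33 (SE 0.35) and the loci AT4G15670, AT4G15690 and AT4G15700 by 2.11, 2.07 and 1.72, while EXPA8 fell by 1.38 (SE 0.23) and ARL, an organ growth gene, by 1.26 (SE 0.26). None of the 4 measured touch and early stress genes was called in either tissue, and camera called none of the 9 lists in either. That list fixed 24 genes. Of the measured ones CML37, CML38 and CML39 stood at 0.84 to 1.46 in the control and touch groups, near the low end of the signals. So the result does not show that touch and stress genes did not respond. COR15A and EXPA16, which rose in the tip under both FR treatments, changed there by 0.82 (SE 0.19) and 1.06 (SE 0.29) under touch. They were not called over all probe sets, but rose adjusted over their list alone. IAA29 had a log2 change of -0.43 (SE 0.31) in the tip and 0.18 (SE 0.31) in the base. Limma called 43 probe sets in the tip (16 without touch leaf tip replicate 2 and 24 without replicate 1), where 1634 had an unadjusted p under 0.05. With only the groups compared, limma called 0.

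In the petiole base AT1G57590 rose by 1.67 (SE 0.34) and the glutathione transferase gene GSTU23 by 1.22 (SE 0.19), and AT1G06360 fell by 2.17 (SE 0.33). Limma called 37 probe sets there, where 1896 had an unadjusted p under 0.05, and 0 with only the groups compared. That count rests on single arrays. It was 483 without control petiole base replicate 2, 0 without touch petiole base replicate 2, 2 without control replicate 3, 3 without touch replicate 3 and 8 without control replicate 1.

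Whole FR against local FR asks what light on the rest of the plant added. In the petiole base IAA29 was higher under whole FR by 3.83 (SE 0.31), XTH33 by 2.62 (SE 0.21) and FHL by 2.56 (SE 0.27), and DFR was lower, at -3.99 (SE 0.32), as was UF3GT, at -3.65 (SE 0.34). Of the 13 cell wall genes 6 were higher and 3 lower (camera adjusted p = 1.277e-05, and 0.000954 with an estimated correlation). Limma called 958 probe sets, 539 higher and 419 lower. In the leaf tip, which was lit in both, no list was called. RR16 was lower under whole FR, at -1.08 (SE 0.24), and the loci AT4G15680, AT4G15670 and AT4G15690 were lower, at -2.42, -1.89 and -1.71. Limma called 390 probe sets in the tip, 142 higher and 248 lower, but 11 with only the groups compared. Without 1 array it called 195 (local FR leaf tip replicate 3), 240 (local FR replicate 2) and 216 (whole FR replicate 1).

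**Figure D4:**
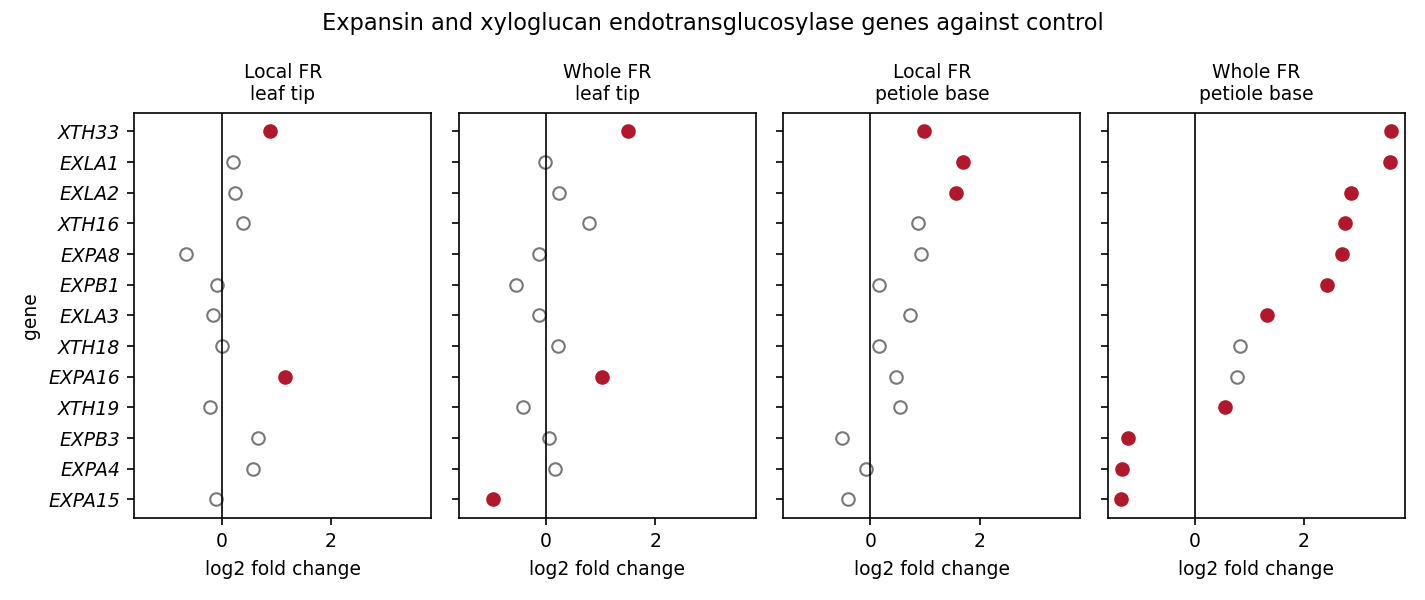
Log2 fold change against control of the 13 measured expansin and xyloglucan endotransglucosylase genes under local and whole FR, with filled points for called genes and open points for the rest. In the petiole base 3 are called under local FR and 11 under whole FR.

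The calls of both FR treatments were set side by side in each tissue. Of 359 calls under local FR in the tip 296 were also called in the same direction under whole FR, and of 186 in the base 171 were, with 0 in opposite directions. Both sets are measured against the same 3 control arrays, which by itself gives a correlation of 0.50 across probe sets in simulated arrays without any effect. No call was shared in 50 simulations, but arrays without an effect leave hardly any calls to share. That count therefore does not show what the shared control arrays add to the shared calls. The measured correlations were 0.71 in the tip and 0.67 in the base. Local FR and touch shared 16 calls in the same direction in the tip, 6 higher and 10 lower, where 0.316 and 0.141 were expected from the numbers of calls. In the base 3 were called in the same direction and 1 in opposite directions. Their correlations, 0.47 and 0.29, lay below 0.50, which effects of each treatment alone can bring about. Their covariances were 0.0354 in the tip and 0.0206 in the base, against 0.0196 in the simulated arrays of each tissue.

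Local FR against touch compares the treatments directly, so a difference can come from the response to either of them. In the leaf tip GH3.3 was higher under local FR by 4.65 (SE 0.53), IAA34 by 3.63 (SE 0.18), IAA29 by 3.33 (SE 0.31) and YUC2 by 1.83 (SE 0.23), and limma called 242 probe sets, or 118 with only the groups compared. Without 1 array it called 140 and 153 (local FR leaf tip replicates 2 and 3) and 154 and 136 (touch leaf tip replicates 1 and 2). In the petiole base EXLA2 was higher by 2.02 (SE 0.21), HAT2 by 1.64 (SE 0.19) and IAA29 by 1.49 (SE 0.31), and the gibberellin receptor gene GID1A was lower, at -0.94 (SE 0.15). Limma called 667 probe sets there, 259 higher and 408 lower. With only the groups compared it called 400. Without 1 array it called 321 and 326 (local FR petiole base replicates 2 and 3) and 442, 385 and 353 (touch petiole base replicates 1, 2 and 3). The 2 groups lay on opposite sides of control on a score along the tip-minus-base difference of the whole FR arrays. Local FR averaged -0.1 ± 0.051 (SD, n = 3), touch 0.079 ± 0.008 and control 0 ± 0.045, so a difference in tissue position was not told apart from light. On the petiole base arrays alone limma called 461, and 44 with the tip-minus-base score of the control arrays added as a covariate, a choice made after seeing the data. With that covariate all 667 kept their sign, at a median of 0.740 of their fold change. With the score of the whole FR arrays, which carry the far-red response themselves, limma called 0 (1397 at an unadjusted p under 0.05), and 511 of the 667 kept their sign, at a median of 0.469.

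Whether a treatment acted differently at the 2 ends of the leaf was tested as a difference of effects. The local FR effect differed for 159 probe sets, or 76 with only the groups compared and 105 without local FR petiole base replicate 2. GH3.3 rose more in the tip by 4.76 (SE 0.75) and IAA34 by 3.36 (SE 0.25), while EXLA1, at -1.49 (SE 0.26), and EXLA2, at -1.32 (SE 0.30), had the higher effect in the base. Of the 13 cell wall genes 3 had the higher local FR effect in the base, 1 in the tip and 9 did not pass the test, and the list was not called (camera adjusted p = 0.0540, and 0.0772 with an estimated correlation). The whole FR effect differed for 1464 probe sets, and the cell wall list was shifted towards the base, with 8 genes higher there, 2 higher in the tip and 3 not called (camera adjusted p = 4.438e-06, and 0.000617 with an estimated correlation). The touch effect differed for 0 probe sets in limma, with 1507 at an unadjusted p under 0.05 where chance gives 875.2, and for 21 without control petiole base replicate 2. Calls in tip and base overlapped in 22 probe sets under local FR, 19 in the same direction, where 3.82 were expected (Fisher's exact p = 3.744e-11). Under whole FR they overlapped in 437, with 344 in the same direction and 93 in opposite directions, where 183.7 were expected (Fisher's exact p = 8.531e-77). Both tests take probe sets, and tip and base arrays, as independent. Probe sets are not, and tip and base came from the same leaf.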

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

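The tests of a wrong label, of the cutting position, of a shared replicate round, of the direction of change and of the array floor were chosen only after the results had been seen, and so were the tip-minus-base score as a covariate, the regrouping that moves tip and base together and the counts for a weaker dose with 1 array left out or with arrays not used to choose the probe sets. The differences in effect between leaf tip and petiole base given next were picked out by a test of that difference, and the other patterns below were noticed in the data.

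The local FR effect differed between the tissues for 159 probe sets. Of 100 regroupings of the arrays within each tissue, the real one included, 2 gave as many, and the highest of the others gave 182. The regroupings mix treated with control arrays within each tissue, so they take the treatment as without effect in both. They do not ask whether the effect was equal in both, and cannot exclude chance for a difference between the tissues. They also treat tip and base arrays as independent, but the labels say that both pieces came from the same leaf. Moving same-numbered tip and base arrays together leaves 10 splits, too few for a share under 0.05, with 159 in the real one and 7 in the highest of the others. The effect was higher in the tip for GH3.3 by 4.76, AT3G21330 by 3.83, AT2G47780 by 3.75, AT1G70640 by 3.44 and IAA34 by 3.36. The difference was negative for AT5G17700 at -2.92, PHE1 at -2.60, AT2G30930 at -2.39, AT1G06360 at -2.37 and AT5G16170 at -2.20. Such a sign can come from a fall in the tip. AT5G17700 stood at 3.9, 5.153 and 5.141 in the control tip and at 2.059, 1.796 and 1.976 under local FR. In the base it stood at 4.703, 5.276 and 5.092 against 5.177, 5.214 and 5.072. AT1G06360, AT5G16170 and AT2G30930 were also lower on every local FR tip array than in the control tip. In the base PHE1 and AT2G30930 were higher on every local FR array than in control. Among list members EXPA8 was at -1.57, EXLA1 at -1.49, PIF7 at -1.42 and EXLA2 at -1.32.

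The whole FR effect differed for 1464 probe sets, and 1 of 100 regroupings, the real one, gave as many, with 1220 in the highest of the others. The same limits hold here, so chance is not excluded for the difference. Of the 10 splits that move tip and base together the real one gave 1464 and the highest of the others 1. The differences were 6.36 for GH3.3, 5.04 for UF3GT, 4.50 for AT2G47780, 4.2 for CHIL and 4.04 for DFR. UF3GT and DFR started at 1.45 and 2.02 in the control tip, where a fall as large as in the base cannot register, so for them the difference need not be one of response. They were -4.74 for AT1G06360, -4.67 for ACT11, -4.39 for AT3G05150, -4.11 for AT4G33420 and -4.06 for AT5G45670. Of 13 cell wall genes 8 had negative differences, among them EXLA1 at -3.57, EXPB1 at -3.00 and EXPA8 at -2.82, while EXPA4 at 1.48 and EXPB3 at 1.29 had positive ones and 3 did not pass the test. Negative differences were also found for IAA29 at -2.16, RR16 at -1.25, HYH at -1.15 and PIF7 at -0.83. Positive differences were found for UGT78D2 at 1.80, KIN1 at 1.47, COR15A at 0.87, GID1A at 0.83, LHCB4.2 at 0.79, and PORB and UGT78D1 at 0.77 each. For the touch effect all 100 regroupings gave at least as many as the real 0, the highest 25, so chance is not excluded.

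Other splits were also counted for each comparison of 3 arrays with 3. These designs make 10 splits, too few for a share under 0.05, and in each comparison 1 of the 10, the real one, gave as many calls. Against control in the leaf tip the real and highest other counts were 359 and 1 for local FR, 1384 and 2 for whole FR, and 43 and 3 for touch. In the petiole base they were 186 and 112 for local FR, 2323 and 9 for whole FR, and 37 and 18 for touch. For whole FR against local FR they were 390 and 2 in the tip and 958 and 2 in the base. For local FR against touch they were 242 and 3 in the tip and 667 and 1 in the base, and for tip against base 5028 and 3.

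Control petiole base replicate 2 stood apart from replicates 1 and 3, and without it touch in the petiole base gave 483 calls in place of 37. A strong replicate round shared by arrays of that number is argued against, since their deviations correlated at a mean of 0.07, under the bound of 0.3. A weak one stays open. The deviations of replicate 2 correlated with those of the other arrays numbered 2 at 0.03 to 0.18, a mean of 0.09. Arrays of different groups and numbers correlated at a mean of -0.03. A touch array under a control label stays open: its deviations correlated with the touch arrays at a mean of 0.30 ± 0.07 (SD over 3 arrays), where touch arrays correlated with each other at 0.40 to 0.45 and the other control arrays with touch at a mean of 0.03. A piece cut nearer to the blade stays open too: its slope on the tip-minus-base difference of the whole FR arrays was 0.076. That lies below the largest of the other 11 petiole arrays, 0.088, by less than 0.046, the SD over all petiole base arrays. For the whole FR arrays themselves the difference of the control arrays was used. Bounds as first written counted against both the label and the cutting position, and a margin beyond the spread was required only after the values had been seen.

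Genes moved in the petiole base under local FR, away from the lit tip, and pieces with another share of blade-side tissue may contribute. On the petiole base arrays alone 110 of the 186 probe sets stayed called, and 29 with the tip-minus-base score of the touch arrays added, which met a bound of 25% written before that fit but after the scores had been seen. That bound does not decide, since the covariate left all 186 signs and a median of 0.953 of the fold change, while the median SE went from 0.185 to 0.176 on those arrays alone and to 0.214 with the score, which differed between the groups. A test by direction did not decide either, with 137 of 186 moving as a changed share would give, 73.7% with an SE of 3.23, within that SE of the bound of 75%. A log-linear prediction of sizes gave a median change of 0.0359 where 0.956 was measured. It was set aside because mixing is not linear on that scale, a limit that the covariate score, also on the log scale, shares. A weaker dose of the same light at the base stays open as well. Of the 186, 14 moved further under local than under whole FR, 7.53% with an SE of 1.93, past a bound of 5% written in advance by more than that SE, but leaving out 1 array gave as few as 12, 6.452%, and the local FR arrays that chose the probe sets also enter that contrast. Chosen by 2 local FR arrays and measured in the one left out, 3.665% (SE 1.36) of 191 moved further under local FR in replicate 1, 10.26% (SE 3.435) of 78 in replicate 2 and 5.344% (SE 1.965) of 131 in replicate 3, which does not decide. The margin asked of this bound was changed more than once after the value had been seen. The SEs of these percentages, and of the direction test, are binomial over probe sets, which are not independent. They do not measure the spread between arrays. Of the 186, 182 had the same sign under whole FR, at a median of 0.668 of its size, and 101 moved further under whole FR. These counts do not decide for a dose, since whole FR lit the tip as well. The signs and sizes also rest on the same 3 control arrays. A signal from the tip was not tested.

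All 3 measured flavonoid list genes fell under whole FR in the petiole base, and none passed the test in the tip. Whether the tip levels were too near the floor of the array for a fall to show stays open. All 3 lay less above the 5th percentile of the control tip, 1.02, than they fell in the base: DFR stood 1 above it against a fall of 4.23, UGT78D2 1.60 against 1.81 and UGT78D1 0.32 against 0.73. But that percentile comes from other probe sets, and DFR and UGT78D2 lay at percentiles 44.42 and 50.38 of the control tip. Under whole FR they changed in the tip by -0.19 (SE 0.32) and -0.01 (SE 0.36). For UGT78D2 a fall down to 1.02, by 1.60, would have shown. For DFR such a fall, by 1, might not have passed the test over all probe sets. The floor of each probe set itself is not known. A floor cannot give the change of CHIL, a chalcone isomerase-like gene outside the list and singled out after its values were seen, which rose in the tip by 2.17 (SE 0.31, adjusted p = 6.468e-05) and fell in the base by 2.03 (SE 0.31, adjusted p = 6.23e-05). For CHIL the response differed between the tissues, and for the 3 list genes a response of the base alone stays open.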

How the results depend on the processing

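The fit of petiole base arrays alone, the covariate score, the block by leaf and the block with only the groups compared were chosen after seeing the data. Counts stayed within 1.5 times under cyclic loess and the filter on dim probe sets in all 14 comparisons. The balance of directions was less stable. Whole FR in the tip, with 702 higher and 682 lower, gave 648 and 737 under cyclic loess, 1282 and 1618 with all probe sets, 723 and 733 with a variance trend and robust estimation, and 348 each with only the groups compared. Whole FR in the base, with 1256 and 1067, gave 1134 and 1199 under cyclic loess. The difference of local FR effects, with 78 and 81, gave 79 and 77 under cyclic loess and 117 and 107 with all probe sets, and that of whole FR effects, with 716 and 748, gave 740 and 714 under cyclic loess. Leaving out 1 array also turned the balance: for whole FR in the tip without control leaf tip replicate 1 (531 and 575), 2 (589 and 592) or 3 (529 and 561) or whole FR leaf tip replicate 1 (481 and 494), and for touch in the tip, with 27 and 16, without control leaf tip replicate 1 (16 and 17), 2 (20 and 24) or 3 (23 and 30). Touch in the base, with 27 and 10, gave 232 and 251 without control petiole base replicate 2. The difference of local FR effects gave 65 and 60 without control petiole base replicate 3 and 62 and 61 without local FR leaf tip replicate 3, and that of whole FR effects 743 and 700 without control petiole base replicate 3. Of 277 called results for named genes 273 kept their sign under every alternative run. Under every alternative chosen before the data were examined, other than leaving out arrays, 193 stayed called wherever their probe set was tested. The filter on dim probe sets tested 407 of the 423 results for named genes, called or not.

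With only the groups compared, which leaves fewer arrays to estimate the spread, local FR gave 126 calls in the tip and 27 in the base, whole FR 696 in the tip, touch 0 in both, whole against local FR 11 in the tip, local FR against touch 118 in the tip and 400 in the base, and the difference of local FR effects 76. With all probe sets of the file, unnamed ones included, more were tested: local FR gave 556 and 327 in tip and base, whole FR 2900 and 4266, whole against local FR 788 and 1744, local FR against touch 418 and 1058, tip against base 9725 and the difference of whole FR effects 2584. With a variance trend and robust estimation touch gave 85 in the base and its difference of effects 3. For these last the cause was not tested.

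With the replicate block touch gave 62 in the base. With the block and only the groups compared local FR gave 26 in the base. With a block by leaf the difference of touch effects gave 1. Same-numbered tip and base arrays correlated in their deviations at 0.0130 to 0.129, and 10 of 12 best with their own number, a hint from the data and not the design. On the petiole base arrays alone local FR gave 133, touch 0 in limma (1963 at an unadjusted p under 0.05) and local FR against touch 461. With the tip-minus-base score added to that fit local FR gave 34 (touch arrays' score), touch 0 (whole FR arrays' score, 1093 unadjusted) and local FR against touch 44 (control arrays' score) and 0 (whole FR arrays' score, 1397 unadjusted). In this last AT4G22485 (-1.69), AT3G28220 (0.46), AT1G14250 (0.34) and AT1G64370 (0.59) reversed without passing the test, and of all 667 probe sets called for that comparison 511 kept their sign. The whole FR arrays carry the far-red response themselves, so their score can remove it, and for the others the cause was not tested.

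Leaving out 1 array gave these ranges against control: in the tip 213 to 314 for local FR, 975 to 1181 for whole FR and 16 to 53 for touch, in the base 78 to 220, 1819 to 2203 and 0 to 483. Whole against local FR ranged from 195 to 358 in the tip and 650 to 791 in the base, local FR against touch from 136 to 222 and 321 to 748, and tip against base from 4231 to 4815. The differences of effects ranged from 105 to 160 for local FR, 1173 to 1443 for whole FR and 0 to 21 for touch. Low signal limits falls: a gene near the array floor cannot show one.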

Other observations

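Gene families read from shared symbols, a choice made after the annotation had been seen, add to the account of whole FR in the petiole base. All 5 measured beta-tubulin genes of the TUB family rose, with a median log2 change of 0.78 (camera adjusted p = 0.000145, and 0.0252 with an estimated correlation). Of 5 CSLC genes, which code for synthases of the xyloglucan backbone, 4 rose, with a median of 0.70, and of 15 SEC genes of vesicle traffic 6 rose, with a median of 0.42. Both had a camera adjusted p of 0.000343, and 0.0325 with an estimated correlation. Of 5 CRR genes, which serve the chloroplast NDH complex, 4 fell, with a median of -0.65 (adjusted p = 0.0467 with an estimated correlation). Under local FR in the petiole base 2 of 9 BZIP genes rose and none fell, with a median of 0.38 (camera adjusted p = 0.000141, and 0.00927 with an estimated correlation). Of 58 families tested in 7 comparisons, 29 results from 16 families passed with the preset correlation, and 7 of them also with an estimated correlation.

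Probe sets without a name in the platform annotation moved as well. In the fit of all probe sets 2155 of them were called under whole FR in the petiole base, 1053 higher and 1102 lower, and 179 under local FR there, 136 higher and 43 lower.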
